A study of Homo sapiens with 12 samples.

How the data were processed

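RNA levels were measured in Calu-3, an established human airway epithelial cell line, on 12 arrays with probe sets for whole transcripts. Per the labels, 6 arrays carried cells transfected with NC1, a scrambled control RNA, 3 arrays cells transfected with a small interfering RNA against SIN3A, and 3 arrays cells transfected with a mimic of the microRNA miR-138. The labels name Calu-3, while the extraction notes speak of primary cultures. The labels were followed, and which cells were measured could not be settled further. Per the submitters' protocol notes, the RNAs were delivered with a lipid reagent, RNA was extracted with TRIzol, and 5 µg of total RNA was labelled with the array maker's one-cycle kit. The doses and the time between transfection and harvest are not given in the sources used here.

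The deposited values are in log2 units, 1 per probe set and array. Per the submitters' processing notes, RMA and Partek 6.3 were used, without a statement of which step each one did. The values of all arrays lay between 1.43 and 13.2 with array medians of 5.09 to 5.16, as RMA values on the log2 scale do, and they were used as deposited. No scanner images were used, so background, normalization and summary of the probes stand as the authors left them. Arrays give no counts, so the number of arrays limits the precision, and the median standard error of a log2 difference from the NC1 control was 0.10.

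The table held 33297 probe sets, of which 19460 carried 1 gene symbol, 1754 several and 12083 none. Each gene was represented by the probe set with 1 symbol and the highest mean level over all 12 arrays, which gave 18417 genes, 769 of them with more than 1 such probe set. Dim probe sets were not removed. Probe sets without a single symbol were tested apart from the genes.

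All 12 arrays were fitted with 3 group means in limma 3.58.1 under R 4.3.3, with moderated variances and 9 residual degrees of freedom. The contrasts were SIN3A siRNA against NC1 control, miR-138 mimic against NC1 control, and miR-138 mimic against SIN3A siRNA. In this fit, arrays outside a contrast bear on its calls only through the variance that all groups share. A gene was called at an adjusted p (Benjamini-Hochberg, over all 18417 genes) under 0.05. Standard errors are those of the limma fit, and spreads of groups are SD. For SIN3A and CFTR an exact two-sided permutation test over arrays was added. With 3 arrays against 6 there are 84 splits and the smallest exact p is 0.0119, and with 3 against 3 it is 0.1.

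30 gene lists (926 genes, 844 measured) were fixed in advance, together with the groups, the contrasts and the rule for naming genes. They covered the SIN3-HDAC complex, reported miR-138 targets, RNA interference, the handling of CFTR in the cell, stress, inflammation, proliferation, metabolism, adhesion, and markers of airway and other cell types. They were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 30 lists, and beside it with an estimated correlation and with fry, whose p asks whether a list's genes move one way on balance without comparing them with other genes. Members were counted with the adjustment over all genes and adjusted over the list alone. 1 of the lists is counted in the totals but not reported here.

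The rule named SIN3A and CFTR, the 10 genes with the largest rise and the 10 with the largest fall in each contrast with the control among called genes whose treated arrays all lay beyond all NC1 arrays, up to 4 members with the smallest adjusted p from each list described, and the 5 largest in each direction for the contrast of both interventions and for the shared genes. Unnamed loci, small RNA genes and probe sets with several symbols were left out of the naming.

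The NC1 arrays were also compared with each other, replicates 4 to 6 against 1 to 3. They differed (values in the results), and the arrays were placed in 2 sets, NC1 1 to 3 with SIN3A siRNA and NC1 4 to 6 with the miR-138 mimic. These sets are not in the labels and were inferred from the values after these had been seen. The samples are listed in the order NC1 1 to 3, SIN3A siRNA, NC1 4 to 6 and miR-138 mimic. That order matches the sets but does not state how the arrays were run. By mean correlation the SIN3A siRNA arrays stood less clearly with 1 part than the mimic arrays did. They were closer to the mimic arrays (mean r 0.984) than to NC1 1 to 3 (0.980). Along the line from NC1 1 to 3 to NC1 4 to 6, the siRNA arrays lay at 0.31 to 0.36 of the way. The mimic arrays lay at 0.62 to 0.66, so both treated groups lay between the parts. Results are therefore given against each part of the control and with the set as a block in the fit (8 residual degrees of freedom), an alternative chosen after the data were seen. A fold change from NC1 in the blocked fit equals that against the NC1 part of the same set, with another standard error. These 2 values are therefore not separate checks. Replicate numbers were not taken to pair the arrays, since the highest correlation between the residuals of arrays with the same number was 0.029. NC1 4 to 6 share no number with treated arrays, and a pairing of them with the mimic arrays was not checked.

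The overlap of both responses was set beside the number that independent lists would give and beside splits of the control in which each contrast had its own 3 NC1 arrays. Their correlation was set beside 50 simulations in which no gene changed. Alternatives fixed before the data were examined were a second quantile normalization, centring of arrays, the lowest 33.3% of genes by mean level left out, all probe sets or their average, only the groups compared, other variance models, array weights, stricter thresholds, either part of the control alone, the replicate number as a block and each array left out in turn. How often other splits of the arrays gave as many calls was counted with fits of the compared arrays alone.

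The pipeline was tested on simulated data in which 200 of the genes were given log2 changes of 0.5 or 1. Without a difference between array sets, 100% of the changes of 1 and 90% (SIN3A siRNA) or 89% (miR-138) of those of 0.5 were recovered, with 8 and 11 false calls. With the measured difference between sets added, 71% and 55% of the changes of 0.5 were recovered without the block, and 62% and 79% with it. That difference was added in full to all arrays of the mimic's set, while the measured treated arrays lay between the NC1 parts. A list shifted by 0.3 was found in each contrast, with 0 of the other lists called. The simulated genes were drawn independently of each other. This does not test how many lists are called wrongly where genes move together. Genes with a miR-138 seed site were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.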

Results

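The 12 arrays gave log2 levels of 18417 genes in Calu-3 cells transfected with a scrambled control RNA (NC1, n = 6), a small interfering RNA against SIN3A (n = 3) or a mimic of miR-138 (n = 3). SIN3A is the scaffold of a histone deacetylase complex that represses transcription, and the series title ties a microRNA network to CFTR, the chloride channel of airway epithelium. The array medians lay between 5.09 and 5.16, and the correlation between arrays across genes lay between 0.968 and 0.993. Genes are not independent replicates. The NC1 arrays fell into replicates 1 to 3 and replicates 4 to 6. The miR-138 mimic arrays were closer to NC1 4 to 6 (mean r 0.985, against 0.979 with NC1 1 to 3). Of the NC1 parts, the SIN3A siRNA arrays were slightly closer to NC1 1 to 3 (0.980 against 0.978). They were closer still to the mimic arrays (0.984), so their place in a set is less certain. Values against each part of the control are therefore given for SIN3A, CFTR, several lists, and those genes with the largest changes in which the parts differed. Values with the array set as a block are given where they change the call of a named gene, and for several lists. The labels call the arrays biological replicates but do not say whether each came from its own culture, so p-values measure the spread between these arrays, which may be technical.

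**Figure D1:**
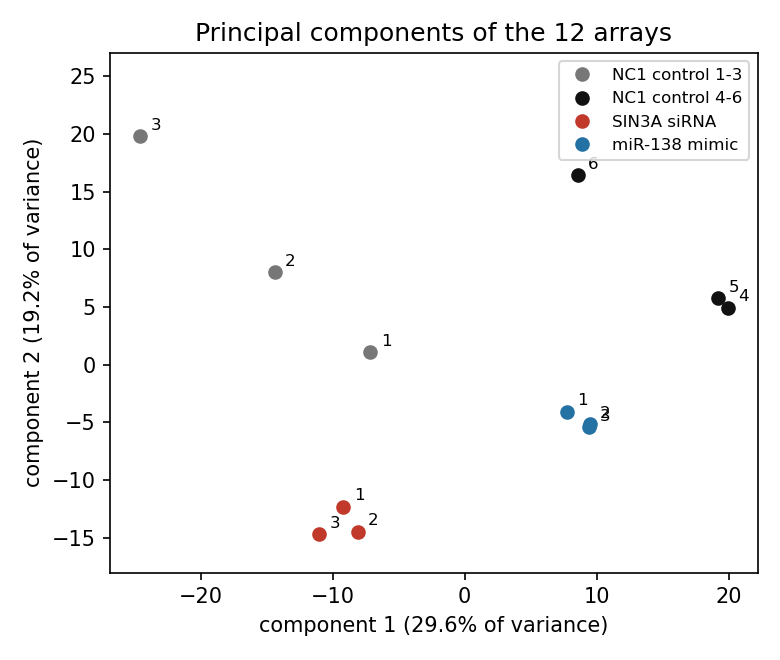
Principal components 1 (29.6% of variance) and 2 (19.2%) of the 12 arrays, each point an array, computed from the log2 levels of all genes. NC1 1 to 3 lie below 0 on component 1, with the SIN3A siRNA arrays, and NC1 4 to 6 lie above 0, with the miR-138 mimic arrays.

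SIN3A mRNA (probe set 7990487) was lower after both interventions. It was 6.91 ± 0.36 (SD, n = 6) with NC1, 6.03 ± 0.14 (SD, n = 3) with SIN3A siRNA and 6.08 ± 0.16 (SD, n = 3) with the miR-138 mimic. This left 54.2% of the NC1 level with the siRNA (log2 fold change -0.88, SE 0.17, limma adjusted p = 0.0111, exact permutation p = 0.0119, the smallest possible) and 56.1% with the mimic (-0.83, SE 0.17, limma adjusted p = 0.0304, exact permutation p = 0.0238). The 2 treated groups did not differ detectably in SIN3A (log2 difference 0.05, SE 0.20, limma adjusted p = 0.953). SIN3A itself differed between the parts of the control, so the fall with the siRNA was -0.59 against NC1 1 to 3 and -1.18 against NC1 4 to 6, and with the mimic -0.54 and -1.13. In the fit with the set as a block SIN3A fell by 0.59 with the siRNA and by 1.13 with the mimic, both called. The call for the siRNA was lost without SIN3A siRNA 2 (adjusted p = 0.0725) or 3 (0.0615). The call for the mimic was lost without NC1 6 (0.0633), any SIN3A siRNA array (0.0503, 0.0504 and 0.0524) or any mimic array (0.202, 0.156 and 0.0841). The siRNA arrays do not enter the fold change with the mimic, only its estimated variance.

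CFTR mRNA (probe set 8135661) fell with SIN3A siRNA to 39.5% of the NC1 level. Its level was 7.95 ± 0.29 (SD, n = 6) with NC1 and 6.62 ± 0.10 (SD, n = 3) with the siRNA, and the highest siRNA array (6.69) lay below the lowest NC1 array (7.46). The log2 fold change was -1.34 (SE 0.14, limma adjusted p = 0.000203, exact permutation p = 0.0119, the smallest possible), or -1.16 against NC1 1 to 3 and -1.51 against NC1 4 to 6. It was -1.16 with the set as a block. With the miR-138 mimic CFTR was 7.56 ± 0.05 (SD, n = 3), 76.1% of the NC1 level, and the difference did not pass the test (-0.39, SE 0.14, limma adjusted p = 0.244, exact permutation p = 0.0833). It was -0.22 against NC1 1 to 3 and -0.57 against NC1 4 to 6. The call was made with the set as a block (-0.57, limma adjusted p = 0.0188), after a second quantile normalization (-0.47, limma adjusted p = 0.0339) and without NC1 3 (-0.49, limma adjusted p = 0.0245). CFTR was 1.93-fold higher with the mimic than with the siRNA (log2 difference 0.95, SE 0.16, limma adjusted p = 0.00932), a call lost with the set as a block (0.60, limma adjusted p = 0.120).

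**Figure D2:**
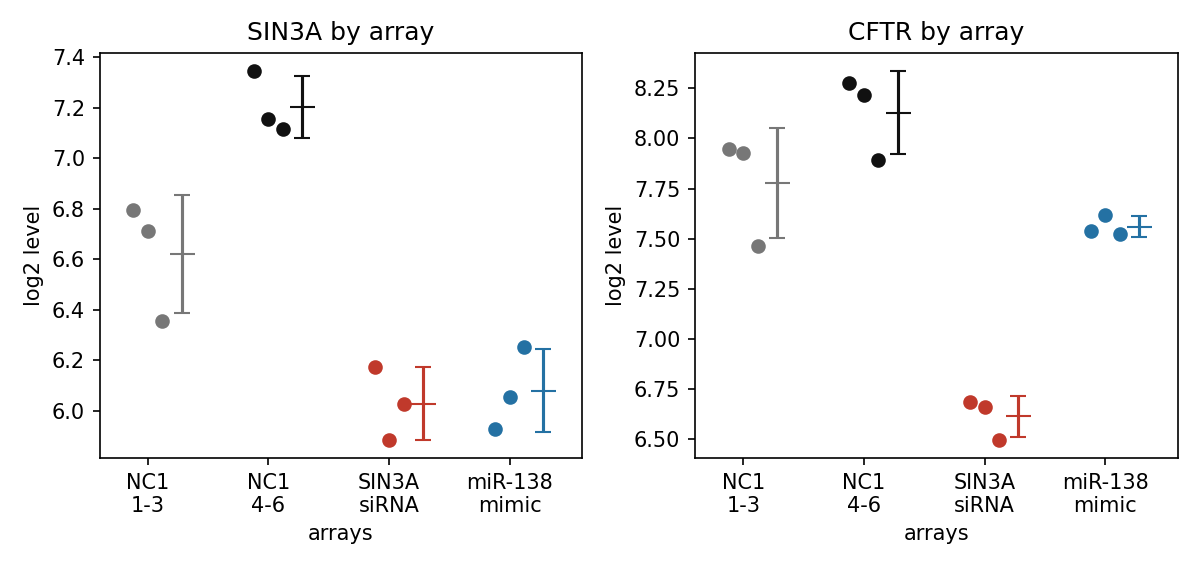
Log2 levels of SIN3A and CFTR on each array, by group, with NC1 1 to 3 and NC1 4 to 6 apart; points are arrays, and the mark beside them is the mean with its SD (n = 3). SIN3A was low in both treated groups (6.03 and 6.08), and CFTR was lowest with SIN3A siRNA (6.62).

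The comparison of SIN3A siRNA with NC1 asked which genes change when the scaffold is depleted. Genes are ranked here among called ones whose siRNA arrays all lay beyond all NC1 arrays. Beside CFTR, the largest falls were those of SNX10, a sorting nexin of endosomes (2.70-fold lower, log2 -1.43, SE 0.22), MOB1A, an activator of the Hippo pathway kinases (log2 -1.31, SE 0.15), and TYMS, thymidylate synthase (log2 -1.30, SE 0.24). Then came FAM111B (-1.26), EMP2, a membrane protein of epithelia (-1.26, SE 0.11), and HELLS, a helicase of the chromatin remodelling kind (-1.25). RCN1, a calcium-binding protein of the endoplasmic reticulum (-1.07), PALMD (-1.07) and OLFM4, a secreted glycoprotein (-1.06, SE 0.08), followed. The largest rises were those of AKR1B10, an aldo-keto reductase (2.52-fold higher, log2 1.33, SE 0.26), and ITGA2, the integrin subunit alpha-2 (log2 1.31, SE 0.12). Next were the cytokine gene IL1A (1.20, SE 0.31) and CHORDC1, a partner of the chaperone HSP90 (1.16, SE 0.20). CAPRIN2 (1.10), TMEM120B (1.07), SEMA7A (1.05), UQCC5 (0.99), PIGH (0.99) and the proton pump subunit gene ATP6V1D (0.96) followed. Their n is 3 against 6 arrays. For 10 of these genes the parts of the control differed (limma adjusted p under 0.05), so the size of the change depended on the part. Against NC1 1 to 3 and NC1 4 to 6, IL1A was at 0.55 and 1.86, AKR1B10 at 0.82 and 1.84, and CHORDC1 at 1.45 and 0.87. Of the 10 rises that of IL1A was the smallest against NC1 1 to 3. The falls were -1.03 and -1.84 for SNX10, -0.83 and -1.78 for TYMS, -0.74 and -1.79 for FAM111B, and -0.74 and -1.76 for HELLS. PALMD was at -0.63 and -1.51, MOB1A at -1.08 and -1.55 and EMP2 at -1.06 and -1.46.

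In all, 739 genes were called (limma), 433 higher and 306 lower. The balance depended on the control arrays: 569 higher and 315 lower against NC1 1 to 3 alone, and 1162 and 1406 against NC1 4 to 6 alone. Without NC1 3 it was 488 and 545. 444 genes were called against each part alone in the same direction and 44 in opposite directions. The 3 siRNA arrays lay above all NC1 arrays for 1011 genes and below them for 651, together 9.02% of genes where chance gives 2.38%. The fit with the set as a block called 1050 genes, 497 of them in both fits with the same sign. Among the genes above, PIGH lost its call with the block (adjusted p = 0.120), and a further probe set of TMEM120B showed a log2 change of 0.16. Left without 1 array, the calls of IL1A (highest adjusted p = 0.173) and PIGH (0.189) depended on most arrays. AKR1B10, FAM111B, HELLS and PALMD depended on each siRNA array (highest adjusted p 0.0712, 0.0859, 0.0846 and 0.112). TYMS depended on SIN3A siRNA 2 (0.0536), and the other genes above kept their calls. Without SIN3A siRNA 1, 2 or 3 the count was 254, 191 or 165 genes.

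Genes of mitochondrial oxidative phosphorylation rose together with SIN3A siRNA: 8 of 36 measured members rose and 0 fell (17 higher and 1 lower adjusted over the list alone). Among them were subunit genes of complex I, NDUFA5 (log2 0.66), NDUFB10 (0.52) and NDUFB8 (0.44), and of complex IV, COX5B (0.55, SE 0.09). The list was called by camera (adjusted p = 1.02e-09, and adjusted p = 0.104 with an estimated correlation). The list of the secretory pathway and CFTR trafficking rose as well, with 5 of 47 members higher and 0 lower (11 higher and 1 lower adjusted over the list alone), among them the vesicle fusion gene VAMP8 (0.50) and the COPII coat genes SEC24A (0.49) and SEC31A (0.43). Its adjusted p was 4.65e-07 (adjusted p = 0.236 with an estimated correlation). In the list of autophagy and lysosome 4 of 33 members rose and 0 fell (12 higher adjusted over the list alone), with the galactosidase gene GLA (0.58), ATG16L1 (0.48) and the sterol carrier gene NPC2 (0.44). This list had an adjusted p of 2.35e-05 (adjusted p = 0.0617 with an estimated correlation). Of 28 proteasome genes 4 rose and 1 fell (6 higher and 1 lower adjusted over the list alone). PSMA5 was at 0.60, PSMD8 at 0.54 and PSMA2 at -0.47, and the list was called (adjusted p = 7.46e-05, adjusted p = 0.521 with an estimated correlation). Its median was 0.27 against NC1 1 to 3 and 0.08 against NC1 4 to 6, where it was not called (adjusted p = 0.202).

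Genes of the G1/S transition and DNA replication fell with SIN3A siRNA: 7 of 39 fell and 0 rose (10 lower and 1 higher adjusted over the list alone). Beside TYMS these included the polymerase gene POLA1 (log2 -0.92, SE 0.19, with -0.53 against NC1 1 to 3 and -1.30 against NC1 4 to 6), GINS1, part of the replicative helicase (-0.73), and the transcription factor gene E2F8 (-0.65). The list was called lower (adjusted p = 1.14e-07, adjusted p = 0.476 with an estimated correlation), with a median of -0.09 against NC1 1 to 3 and -0.49 against NC1 4 to 6. The replication-dependent histone list had a median of -0.43, although 0 of its 32 members passed alone. It too was called lower (adjusted p = 1.14e-07, adjusted p = 0.476 with an estimated correlation). Its median was -0.07 against NC1 1 to 3 and -0.80 against NC1 4 to 6, and the call was lost with the set as a block (adjusted p = 0.0574). Of 29 mesenchymal genes 2 fell and 0 rose, which was also the count adjusted over the list alone. They were THBS1, a matrix glycoprotein (-0.64), and the growth factor gene TGFB2 (-0.62). The adjusted p of that list was 0.0365 (adjusted p = 0.236 with an estimated correlation, and 0.126 with the set as a block). Of the 8 lists called, 5 were called in the same direction against each part of the control alone: oxidative phosphorylation, trafficking and autophagy higher, G1/S and histones lower. With the set as a block 10 further lists were called. SIN3-HDAC (adjusted p = 0.0339), CFTR folding (0.0239), degradation from the endoplasmic reticulum (0.0339), MYC targets (0.00278), glycolysis (0.000737) and cholesterol biosynthesis (0.0339) were higher there. The unfolded protein response (0.0495), secretory airway markers, interferon and NF-kB were lower. Of these 10, interferon and NF-kB alone kept the call with an estimated correlation (adjusted p of the other 8 from 0.0740 to 0.395). By fry 4 lists passed, and with an estimated correlation 0 of 30 did, with 4 at an unadjusted p under 0.05.

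The other 22 lists were not called with SIN3A siRNA (adjusted p 0.0540 to 0.940), yet some members changed. In the list of CFTR folding and chaperones DNAJB1 (0.55) and DNAJA2 (0.47), both HSP40 co-chaperones, rose. The endoplasmic reticulum chaperone genes CANX (calnexin, -0.62, SE 0.11) and HSPA5 (BiP, -0.50, SE 0.11) fell. Adjusted over the list alone, 2 of its 30 members were higher and 3 lower (list adjusted p = 0.751). In the unfolded protein response list HSPA5 and its partner DNAJC3 (-0.53) fell (1 higher and 4 lower adjusted over the list alone, list adjusted p = 0.207). In the list of degradation from the endoplasmic reticulum DERL1 (-0.46) and EDEM3 (-0.52) fell and ERLEC1 (0.44) rose (3 higher and 2 lower adjusted over the list alone, list adjusted p = 0.309). In the airway ion and fluid transport list (adjusted p = 0.176) CFTR, the bicarbonate transporter gene SLC4A4 (-0.91, SE 0.23) and the sodium pump subunit gene ATP1B1 (-0.28) fell and 0 of 33 rose, the same counts as adjusted over the list alone. In the SIN3-HDAC list SIN3A fell and BRMS1 rose (0.43) among 26 members (4 higher and 1 lower adjusted over the list alone, list adjusted p = 0.587). Among 27 p53 targets MDM2 (-0.73) and PLK2 (-0.59) fell, and GADD45A (0.70, with 0.36 against NC1 1 to 3 and 1.05 against NC1 4 to 6) and TIGAR (0.51) rose (3 higher and 2 lower adjusted over the list alone, list adjusted p = 0.571). DNAJA2, EDEM3, ERLEC1, DNAJC3, SLC4A4, ATP1B1, GLA and PSMA2 were no longer called with the set as a block (adjusted p 0.0514 to 0.129). Of the list members named for this comparison CFTR, CANX, COX5B, E2F8, NPC2, PLK2, PSMA5, PSMD8, THBS1 and VAMP8 kept their calls whichever array was left out. The others lost theirs without at least 1 array (highest adjusted p 0.239, for GLA).

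Markers of other cell types did not pass with SIN3A siRNA as lists: basal and squamous (median log2 0.04, adjusted p = 0.389), ciliated (-0.01, 0.751), fibroblast (0.01, 0.934), leukocyte (-0.02, 0.581), endothelial (-0.02, 0.751) and secretory airway markers (-0.04, 0.262). The last of these had a median of -0.21 against NC1 1 to 3 and with the set as a block, where 4 of 24 fell and the list was called lower (adjusted p = 1.61e-05, and adjusted p = 0.0740 with an estimated correlation), and 0.07 against NC1 4 to 6 (adjusted p = 0.122). Single members that fell were DSC3 (-0.57) and LCP1 (-0.38), neither of them called with the set as a block (adjusted p = 0.0780 and 0.0658). With the siRNA 4 lists were called in opposite directions against the parts of the control. Against NC1 1 to 3 and NC1 4 to 6 the medians were -0.17 and 0.13 for NF-kB and inflammatory cytokines, 0.13 and -0.13 for glycolysis and hypoxia, and 0.09 and -0.37 for cholesterol biosynthesis. The interferon response was the fourth: its median was -0.47 against NC1 1 to 3 and 0.18 against NC1 4 to 6, each called. It was -0.13 against all NC1 arrays (adjusted p = 0.0540), where EIF2AK2, the kinase that senses double-stranded RNA, fell (-0.57). Blocked by set, 18 of 35 interferon genes fell and 0 rose (adjusted p = 0.00355 with an estimated correlation). Of 28 genes of NF-kB and inflammatory cytokines 7 then fell and 1 rose (adjusted p = 0.0216 with an estimated correlation), while against NC1 4 to 6 alone 10 were higher and 2 lower and the list was called higher (adjusted p = 3.96e-06). Without the block that list had IL1A higher and CXCL6 lower (-0.51) and was not called (adjusted p = 0.751). Median and mean differed in sign for the reported miR-138 targets (0.04 and -0.01), fibroblast markers (0.01 and -0.01) and p53 targets (-0.002 and 0.03).

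**Figure D3:**
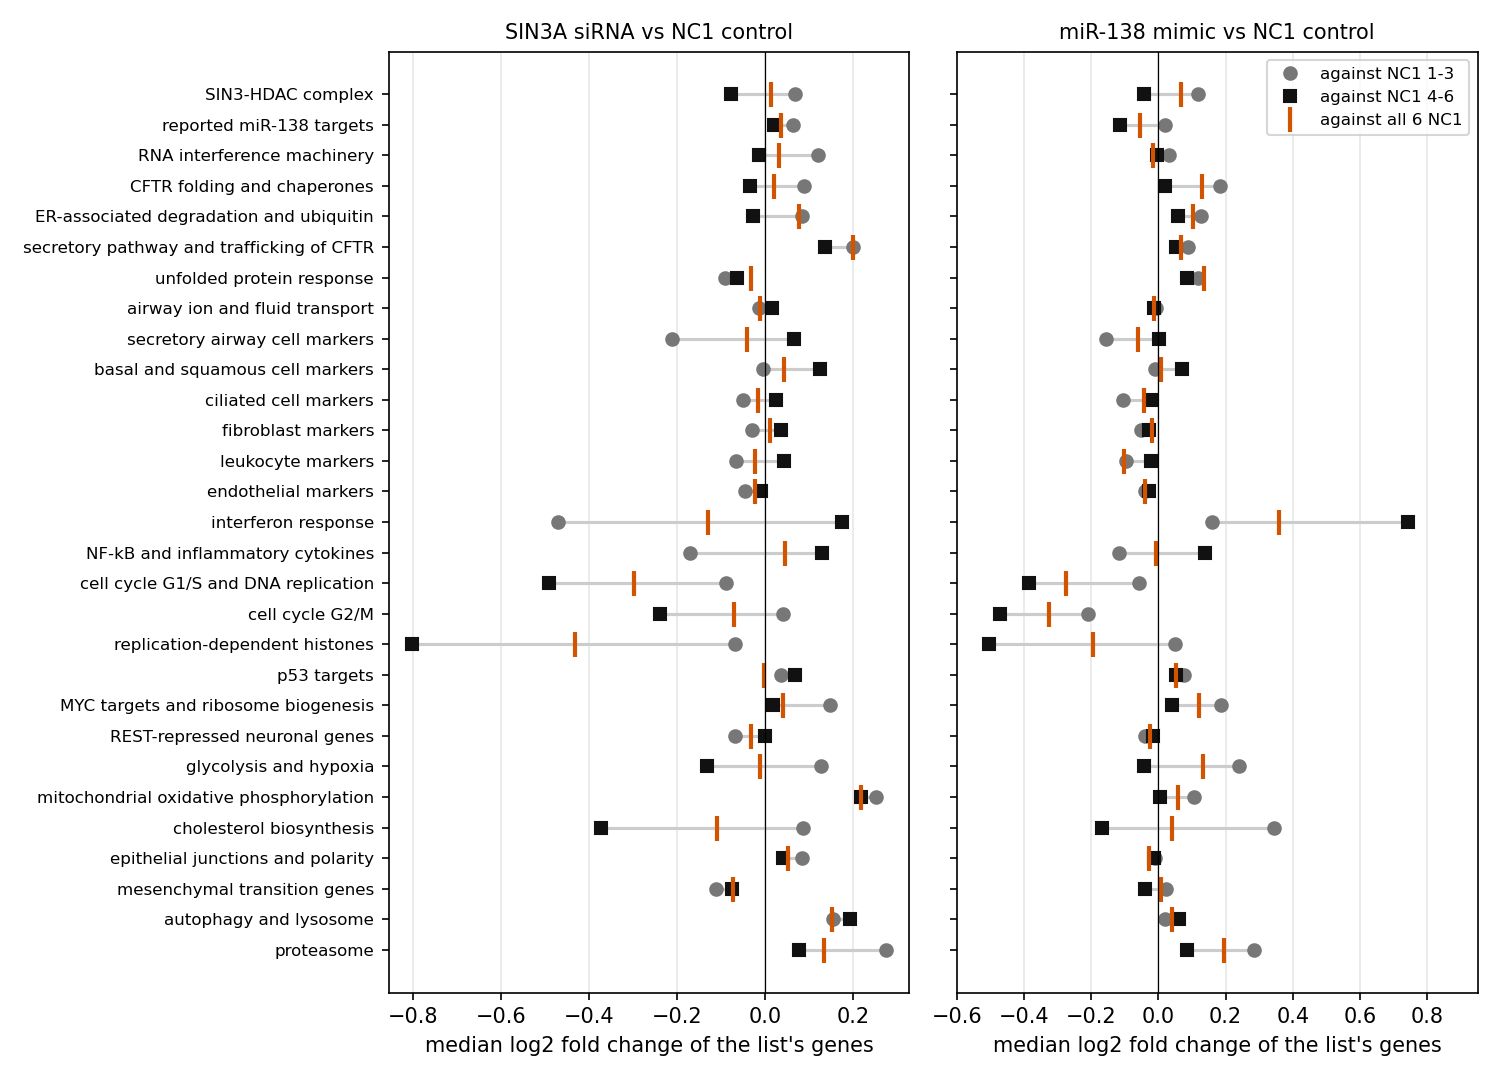
Median log2 fold change of the genes of the lists reported here, for SIN3A siRNA and for the miR-138 mimic, against all NC1 arrays (vertical mark), NC1 1 to 3 (circle) and NC1 4 to 6 (square). With SIN3A siRNA the interferon median was -0.47 against NC1 1 to 3 and 0.18 against NC1 4 to 6, and the oxidative phosphorylation median was 0.25 and 0.22.

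The comparison of the miR-138 mimic with NC1 asked which genes respond to the microRNA. Genes are again ranked among called ones whose mimic arrays all lay beyond all NC1 arrays. The largest falls were those of PCNA, the sliding clamp of DNA replication (2.27-fold lower, log2 -1.19, SE 0.20), KIF20A, a kinesin of cell division (-0.96, SE 0.12), and EMP2 (-0.92, SE 0.11). MOB1A (-0.91), CDKN3, a phosphatase of the cell cycle (-0.90, SE 0.10), and the transcription factor gene NFIB (-0.86, SE 0.10) came next. SIN3A (-0.83), the spindle gene ASPM (-0.82), E2F8 (-0.76) and RERGL (-0.75) followed. The largest rises were those of the pseudogene NMRAL2P (2.27-fold higher, log2 1.18, SE 0.19), IL1RAP, a subunit of the interleukin-1 receptor (1.12, SE 0.22), and THBS1 (1.10, SE 0.10). The guidance factor gene SEMA3A (0.99), INHBA, which encodes an activin subunit (0.99, SE 0.12), and CHORDC1 (0.98) came next. GPR15 (0.97), MCFD2, part of a cargo receptor between endoplasmic reticulum and Golgi (0.97), the microtubule protein gene MAP1B (0.97) and the ubiquitin ligase gene DTX3L (0.94) followed. Their n is 3 against 6 arrays. The parts of the control differed for SIN3A and 10 more of these genes (limma adjusted p under 0.05). Against NC1 1 to 3 and NC1 4 to 6, IL1RAP was at 1.55 and 0.69, MCFD2 at 1.36 and 0.58, SEMA3A at 1.34 and 0.64, CHORDC1 at 1.27 and 0.69, and MAP1B at 1.17 and 0.76. NMRAL2P was at 0.89 and 1.47 and DTX3L at 0.63 and 1.25. PCNA was at -0.82 and -1.55, EMP2 at -0.72 and -1.11 and MOB1A at -0.67 and -1.15.

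In all, 192 genes were called (limma), 118 higher and 74 lower, with 179 of them called against each part alone in the same direction. The 3 mimic arrays lay above all NC1 arrays for 716 genes and below them for 467, together 6.42% of genes where chance gives 2.38%. The fit with the set as a block called 642 genes, 293 higher and 349 lower, 171 of them in both fits with the same sign. Against NC1 1 to 3 alone 1415 genes were called and against NC1 4 to 6 alone 877, with 234 in both in the same direction and 35 in opposite directions. Without miR-138 mimic 1, 2 or 3 the count was 39, 55 or 65 genes. Of the genes above, KIF20A, EMP2, CDKN3, NFIB, E2F8, THBS1, INHBA, GPR15 and MAP1B kept their calls whichever array was left out. PCNA depended on each mimic array (highest adjusted p = 0.0693), and NMRAL2P on mimic 1 (0.0786). MOB1A and ASPM depended on mimic 1 and 2 (0.0800 and 0.107), and SEMA3A on each mimic and siRNA array (0.168). The siRNA arrays bear on these calls only through the shared variance. IL1RAP, CHORDC1, MCFD2, DTX3L and RERGL depended on NC1 arrays as well (0.155, 0.196, 0.184, 0.192 and 0.174).

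Genes of the G2/M phase fell with the miR-138 mimic: 6 of 36 fell and 0 rose (24 lower adjusted over the list alone), with a median log2 change of -0.33. Beside KIF20A these were led by the proliferation marker gene MKI67 (-0.71, SE 0.10), the transcription factor gene FOXM1 (-0.67, SE 0.10) and PTTG1, securin (-0.51). The list had the lowest adjusted p of the 30 (5.80e-21, and adjusted p = 0.235 with an estimated correlation). Blocked by set, 21 of 36 fell and 0 rose (adjusted p = 0.0360 with an estimated correlation). In the G1/S list PCNA and E2F8 fell and E2F7 rose (0.42) among 39 members (9 lower and 1 higher adjusted over the list alone). That list was called lower (adjusted p = 3.19e-07, adjusted p = 0.387 with an estimated correlation). In the blocked fit 19 fell and 1 rose (adjusted p = 0.00613 with an estimated correlation). Its median was -0.39 against NC1 4 to 6, and -0.06 against NC1 1 to 3, where it was not called (adjusted p = 0.331). RRM2, a subunit of ribonucleotide reductase, was at -0.45 without passing (adjusted p = 0.0605), but was called with the set as a block (-0.60, adjusted p = 0.00121). Of 32 replication-dependent histone genes 0 passed alone (1 lower adjusted over the list alone), and H2AC4 was at -0.66 (adjusted p = 0.0813, and -0.91 with an adjusted p of 0.00105 with the set as a block). The histone list was called lower (median -0.19, adjusted p = 0.000371, and adjusted p = 0.514 with an estimated correlation). With the block 20 of its genes fell and 0 rose (adjusted p = 9.28e-05 with an estimated correlation). The histone median was 0.05 against NC1 1 to 3 and -0.50 against NC1 4 to 6. The median of G2/M was -0.21 and -0.47, called lower against each.

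The interferon list rose with the miR-138 mimic, with 2 of 35 members higher and 0 lower (17 higher adjusted over the list alone): EIF2AK2 (log2 0.83, SE 0.14) and IFIT3 (0.74, SE 0.16). RSAD2 was at 1.81 (SE 0.43, adjusted p = 0.0605) and OAS2 at 1.14 (adjusted p = 0.118) without passing. RSAD2 was at 0.89 against NC1 1 to 3 and 2.73 against NC1 4 to 6, and OAS2 at 0.47 and 1.82. Both were called with the set as a block (2.73, adjusted p = 8.74e-09, and 1.82, adjusted p = 2.00e-08). The list adjusted p was 1.40e-10 (adjusted p = 0.372 with an estimated correlation). The median of this list was 0.74 against NC1 4 to 6, and 0.16 against NC1 1 to 3, where it was not called (adjusted p = 0.112). Blocked by set, 24 interferon genes rose and 0 fell (adjusted p = 9.28e-05 with an estimated correlation). In that fit 5 of 28 genes of NF-kB and inflammatory cytokines rose and 0 fell (adjusted p = 0.000593 with an estimated correlation). Against NC1 1 to 3 alone that list was called lower (median -0.12, adjusted p = 0.000531). Without the block it was not called (median -0.01, mean 0.03, adjusted p = 0.491), and its member CXCL8 was at 1.18 (adjusted p = 0.114). CXCL8 was at 0.51 against NC1 1 to 3, and at 1.86 against NC1 4 to 6 and with the block, where it was called (adjusted p = 8.29e-08).

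In the unfolded protein response list HSPA5 rose (0.56, SE 0.11) and 0 of 26 fell (3 higher adjusted over the list alone). PPP1R15A at 0.57 (adjusted p = 0.0969), SEL1L at 0.44 and HERPUD1 at 0.37 were short of the threshold. With the block PPP1R15A (0.84, adjusted p = 7.33e-05) and HERPUD1 (0.52, adjusted p = 0.0224) were called, and SEL1L (0.28, adjusted p = 0.306) was not. This list was called higher against all NC1 arrays (adjusted p = 0.000371, and adjusted p = 0.0550 with an estimated correlation) and against each part. HSPA5 was also the member that rose among 30 genes of CFTR folding and chaperones (1 higher adjusted over the list alone). That list was called higher (adjusted p = 3.34e-05, adjusted p = 0.339 with an estimated correlation), but not against NC1 4 to 6 (median 0.02, against 0.18 for NC1 1 to 3) or with the set as a block (adjusted p = 0.137 for each). Of 28 proteasome genes 0 passed alone or adjusted over the list alone, with PSMD3 at 0.30. The proteasome list was called higher all the same (median 0.20, adjusted p = 4.67e-08, and adjusted p = 0.339 with an estimated correlation). Among 27 MYC targets and ribosome biogenesis genes the nucleolar helicase gene DDX21 rose (0.79, SE 0.10), with 6 higher adjusted over the list alone. Its list was called (adjusted p = 2.26e-05, and adjusted p = 0.339 with an estimated correlation). G2/M, the unfolded protein response, the proteasome and MYC targets were the 4 lists called in the same direction against each part of the control. Of the list members named here MKI67, FOXM1, KIF20A, E2F8 and DDX21 kept their calls whichever array was left out. HSPA5, EIF2AK2, IFIT3, E2F7 and PTTG1 lost theirs without at least 1 array (highest adjusted p 0.139, 0.0848, 0.195, 0.138 and 0.0793).

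A further 6 lists were called with the mimic. Among 33 glycolysis and hypoxia genes NDRG1 rose (0.86, SE 0.14, highest adjusted p 0.0703 without 1 array), with 6 higher and 1 lower adjusted over the list alone. The call (adjusted p = 0.000728, adjusted p = 0.446 with an estimated correlation) was lost with the set as a block (adjusted p = 0.850). The list of degradation from the endoplasmic reticulum was called higher (median 0.10, adjusted p = 0.0207, and adjusted p = 0.372 with an estimated correlation). With the set as a block this call, that of trafficking (both at adjusted p = 0.299) and that of p53 targets (0.133) were lost. The 1 member of the degradation list past the threshold, DERL1, a channel component for that degradation, fell (-0.40) and kept its call only without NC1 3 when 1 array was left out (highest adjusted p 0.243). Autophagy and lysosome had 0 members past the threshold and 3 adjusted over the list alone (median 0.04, adjusted p = 0.0207, and adjusted p = 0.254 with an estimated correlation). The p53 targets had 0 and 2 (median 0.05, adjusted p = 0.0305, and adjusted p = 0.235 with an estimated correlation). In the trafficking list RAB9A, a GTPase of endosome-to-Golgi transport, rose (0.40), with 3 higher and 1 lower adjusted over the list alone. Its call was lost without any array other than NC1 3 or NC1 5 (highest adjusted p 0.238). That list was called (adjusted p = 0.0244, and adjusted p = 0.528 with an estimated correlation). Secretory airway markers were called lower with 0 of 24 members past either threshold (median -0.06, adjusted p = 0.0235, and adjusted p = 0.588 with an estimated correlation), and their median was 0.00 against NC1 4 to 6 and with the block, where the call was lost (adjusted p = 0.850). With an estimated correlation 0 of 30 lists passed, with 4 at an unadjusted p under 0.05, and by fry 3 did.

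Reported miR-138 targets, a list made from general knowledge rather than from these samples, had SIN3A as the 1 member of 25 that fell and 0 that rose (2 lower adjusted over the list alone). The list was not called (median -0.05, adjusted p = 0.113). Blocked by set, 5 members fell and 0 rose (adjusted p = 0.0294 with an estimated correlation). Without SIN3A that block gave 4 lower of 24, and an adjusted p = 0.0508 with an estimated correlation. Among the 26 genes of the SIN3-HDAC list SIN3A fell (median 0.07, adjusted p = 0.455), and PHF12, a protein bound to that complex, was at -0.45 (adjusted p = 0.124), or -0.61 with the set as a block, where it was called (adjusted p = 0.00575). The 16 lists not called (adjusted p 0.113 to 0.733) also held airway ion and fluid transport (median -0.01, adjusted p = 0.526), epithelial junctions and polarity (-0.03, mean 0.02, 0.733) and RNA interference (-0.02, mean 0.01, 0.595). Oxidative phosphorylation (0.06, 0.422), cholesterol biosynthesis (0.04, 0.579; 0.34 against NC1 1 to 3 and -0.17 against NC1 4 to 6, each called), neuronal genes repressed by REST (-0.02, 0.422) and mesenchymal genes (0.01, 0.422) were not called. Basal and squamous (0.01, 0.422), ciliated (-0.04, 0.281), fibroblast (-0.02, 0.303), leukocyte (-0.10, 0.194) and endothelial markers (-0.04, 0.455) were not called either.

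Both interventions changed 54 genes in the same direction, 30 higher and 24 lower. Beside SIN3A, the shared falls were led by EMP2 (log2 -1.26 with the siRNA and -0.92 with the mimic), MOB1A (-1.31 and -0.91), RERGL (-0.80 and -0.75) and SLFN11, which acts at stalled replication forks (-1.05 and -0.74). The shared rises were led by CHORDC1 (1.16 and 0.98), IL1RAP (0.93 and 1.12), SEMA7A (1.05 and 0.83), GPR15 (0.81 and 0.97) and ITGA2 (1.31 and 0.80). The calls for the mimic were lost without mimic 1 for ITGA2 (adjusted p = 0.0540) and without any mimic array for SLFN11 (highest 0.0830). Those for the siRNA were lost without SIN3A siRNA 1 for RERGL (0.0520), and without NC1 2 or any siRNA array for IL1RAP (highest 0.124). Independent lists of these sizes would share 4.00 genes, but these lists are not independent, since both contrasts used the same NC1 arrays. The fit with the set as a block gave 107 shared genes, with 39 of the 54 among them, where independent lists would share 17.8. It also gave 45 genes called in opposite directions, against 18.8. With each response set against its own part of the control, SIN3A siRNA against NC1 1 to 3 and the mimic against NC1 4 to 6, 49 genes were shared against 7.18 by independent lists, and 32 moved in opposite directions against 7.49. The opposite assignment gave 65 shared against 48.9, and 254 in opposite directions against 53.7. Without 1 array the shared genes numbered 10 (without mimic 1) to 86 (without NC1 3).

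A further 6 genes changed in opposite directions, where independent lists would give 3.70, and they are named after their values were seen. HSPA5 fell with the siRNA (-0.50) and rose with the mimic (0.56), as did THBS1 (-0.64 and 1.10), EIF2AK2 (-0.57 and 0.83), APOL1 (-0.64 and 0.75) and APOL2 (-0.33 and 0.42). TPM4, a tropomyosin gene, rose with the siRNA (0.42) and fell with the mimic (-0.46). A further probe set of TPM4 was at 0.23 and -0.28. In the blocked fit APOL2 and TPM4 were no longer called for the siRNA (adjusted p = 0.0677 and 0.0522). Without 1 array, APOL2 and TPM4 lost their calls without any siRNA array for the siRNA (highest adjusted p 0.117 and 0.0800) and without any mimic array for the mimic (0.121 and 0.158). HSPA5 did so likewise (0.115 and 0.139). EIF2AK2 lost its call for the siRNA without any siRNA array, NC1 2, NC1 4 or mimic 2 (highest 0.151) and for the mimic without mimic 2 or 3 (0.0848), while THBS1 and APOL1 kept theirs. Across genes the log2 fold changes of both interventions had a Pearson r of 0.36 and a covariance of 0.0120. In simulations in which no gene changed, the shared control alone gave 0.33 and 0.00328 without a set difference. With the measured difference between the sets added in full, the simulations gave -0.49 and -0.0124. The measured arrays lay less far apart, at 0.31 to 0.36 (siRNA) and 0.62 to 0.66 (mimic) of the way between the NC1 parts. The -0.49 is therefore not the r to expect for these arrays without a change. With the block r was 0.15 and the covariance 0.00591, and with the opposite assignment of control parts r was -0.23.

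**Figure D4:**
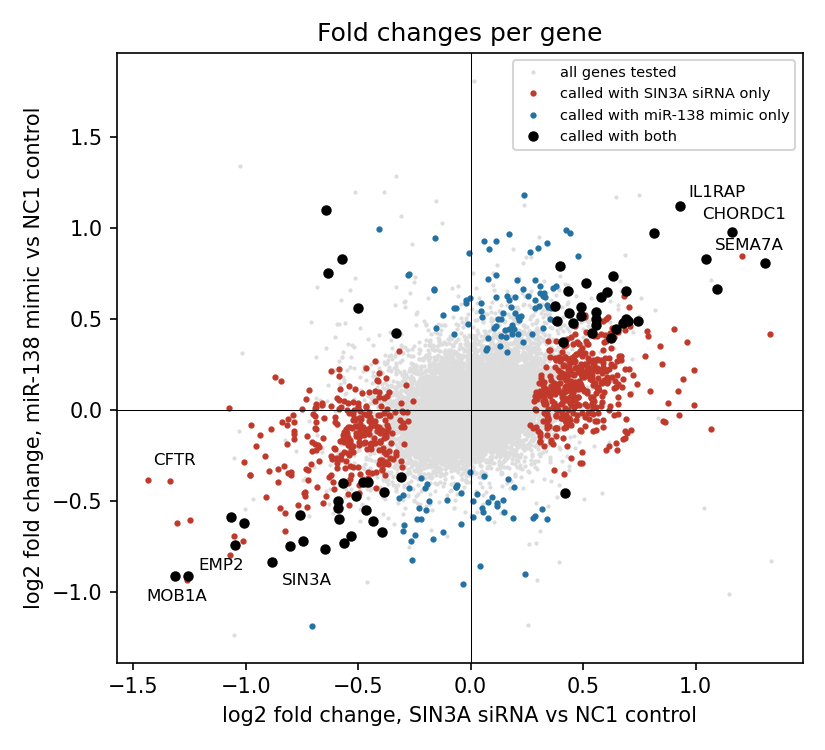
Log2 fold change of each of the 18417 genes with SIN3A siRNA (x axis) and with the miR-138 mimic (y axis) against all NC1 arrays; each point is a gene, coloured where called with either intervention and black where called with both. 54 genes changed in the same direction and 6 in opposite directions.

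For the 2 interventions set against each other, genes were ranked among called ones whose arrays did not overlap. Of those higher with the mimic, the largest differences were in THBS1, 3.34-fold higher (log2 difference 1.74, SE 0.12), and IFI44, an interferon-induced gene (1.72, SE 0.40, and 3.18 with the set as a block). SEMA3A (1.40, SE 0.23), EIF2AK2 (1.40, SE 0.16) and APOL1 (1.39, SE 0.13) were next. DEFB1, an antimicrobial peptide gene (-2.17, SE 0.50), LXN, latexin (-1.23, SE 0.25), TMEM120B (-1.18, SE 0.18), CDKN3 (-1.15, SE 0.12) and NDUFA3 (-1.04, SE 0.21) were lower with the mimic. The further probe set of TMEM120B was at 0.16 with the siRNA and 0.03 with the mimic, each against NC1. In all, 289 genes were called (limma), 125 higher and 164 lower with the mimic. With the set as a block there were 165 higher and 220 lower. The balance of calls turned in fits with NC1 1 to 3 alone (540 higher and 411 lower). It also turned with NC1 4 to 6 alone (857 and 648) and without NC1 3 (294 and 274). In those fits the NC1 arrays do not enter the difference itself, only its estimated variance. All 289 genes stayed called there, and the median log2 difference over all genes stayed at -0.007. The groups did not overlap for 26.4% of genes where chance gives 10%. The fit with the set as a block called 385 genes, 73 of them in both fits with the same sign. DEFB1 (-0.30, adjusted p = 0.394), LXN (-0.43, adjusted p = 0.362), NDUFA3 (-0.35, adjusted p = 0.336) and SEMA3A (0.70, adjusted p = 0.0973) were not called with the block. DEFB1 differed by -1.87 between NC1 4 to 6 and NC1 1 to 3. Without 1 of the 6 treated arrays IFI44, DEFB1, LXN and NDUFA3 lost their calls (highest adjusted p 0.162, 0.149, 0.114 and 0.110), and SEMA3A did without SIN3A siRNA 3 or mimic 2 (0.0578). The count itself was 58 (without mimic 2) to 96 (without SIN3A siRNA 1) with a treated array left out, and 568 without NC1 3.

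Among the lists the unfolded protein response was higher with the mimic than with the siRNA, with 2 of 26 members higher and 0 lower (10 higher adjusted over the list alone), HSPA5 among them (log2 difference 1.06, SE 0.13). It was called with the preset correlation (adjusted p = 0.000104), and it was the 1 list of 9 called that kept its call with an estimated one (adjusted p = 0.0269). It also kept it with the set as a block (adjusted p = 0.0456 with an estimated correlation). Of 30 genes of CFTR folding and chaperones 3 were higher, HSPA5 and CANX (0.84) among them, and 0 lower (6 higher adjusted over the list alone). That list was called as well (adjusted p = 0.0168, adjusted p = 0.632 with an estimated correlation), but not with the set as a block (median -0.04, adjusted p = 0.521). Interferon genes were higher, with 4 of 35 higher and 0 lower (17 higher adjusted over the list alone) and a median of 0.54. The adjusted p was 3.81e-12 (adjusted p = 0.524 with an estimated correlation), and with the set as a block 26 were higher (adjusted p = 8.14e-05 with an estimated correlation). Oxidative phosphorylation was lower with the mimic, with 6 of 36 lower, COX5B (-0.61) and NDUFB10 (-0.54) among them, and 0 higher (17 lower and 2 higher adjusted over the list alone). It had an adjusted p of 8.21e-07 (adjusted p = 0.202 with an estimated correlation). G2/M was lower, with 7 of 36 lower, KIF20A (-0.92) and MKI67 (-0.54) among them (9 lower adjusted over the list alone). Its adjusted p was 2.04e-09 (adjusted p = 0.533 with an estimated correlation). Trafficking (lower, adjusted p = 0.0125, and 0.632 with an estimated correlation) and mesenchymal genes (higher, adjusted p = 0.0121, and 0.202; 0.339 with the set as a block) were called. So were glycolysis and hypoxia (higher, adjusted p = 0.0108, and 0.632) and cholesterol biosynthesis (higher, adjusted p = 0.0286, and 0.852). Both turned with the set as a block and were called lower with the mimic, at medians of -0.16 (adjusted p = 0.0107, and adjusted p = 0.227 with an estimated correlation) and -0.28 (1.07e-06, and 0.0492). Of the 9 calls 5 were made in the same direction with the block, where 15 lists were called. Reported miR-138 targets (lower, adjusted p = 0.0201), NF-kB (higher, 0.000196), G1/S (lower, 0.0492) and histones (lower, 0.00131) were then called with an estimated correlation too.

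The NC1 arrays were compared with each other as a check of the control. In NC1 4 to 6 the acute phase genes SAA1 (log2 -3.67) and SAA2 (-2.32), the cytokine genes IL6 (-2.46) and CCL20 (-1.84) and the interferon-induced genes IFI27 (-2.43), IFITM1 (-2.29) and IFI44L (-2.16) were lower than in NC1 1 to 3. The histone genes H1-3 (1.95), H2BC10 (1.95) and H4C2 (1.86) and the sterol synthesis gene SC5D (1.49) were higher. These genes are named after their values were seen. In all, 1850 genes were called (limma), 1264 higher and 586 lower (1149 without NC1 4 and 1062 without NC1 5). Of 35 interferon genes 24 were lower and 0 higher (adjusted p = 0.000442 with an estimated correlation). Of 28 NF-kB and cytokine genes 12 were lower and 1 higher (adjusted p = 0.000420 with an estimated correlation). Histones (22 of 32 higher and 3 lower, adjusted p = 0.000420 with an estimated correlation) and cholesterol biosynthesis (13 of 20 higher, adjusted p = 0.0103) were called. With an estimated correlation G1/S (20 of 39 higher, adjusted p = 0.0236), glycolysis and hypoxia (14 of 33 higher, adjusted p = 0.0236) and secretory airway markers (6 of 24 lower, adjusted p = 0.0250) were called as well. These parts follow the replicate numbers, and nothing in the labels says how they differ.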

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

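The counts over other splits of the arrays were planned before the data were examined, and the 8 other tests that weigh an explanation here were chosen after the results were seen.

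Among 6 NC1 arrays, a value was singled out where its gap to the next was large for the range (Dixon's test). This held for the mean correlation of NC1 3 with the other arrays (0.974), for CAPRIN2 (5.40), MDM2 (6.57) and RERGL (3.51) in NC1 3, for RHOC (6.71) in NC1 1 and for APOL2 (5.92) in NC1 5. Chance alone singles out about 1 in 20, or 7.25 of the 145 tested, and 6 were seen. Signal also appeared in the 13837 probe sets without a single gene symbol, which no comparison above uses. There 15 were called with SIN3A siRNA (7 higher, 8 lower), 13 between the interventions (6 higher and 7 lower with the mimic) and 0 with the mimic against NC1 by limma, and 42, 18 and 53 with the set as a block.

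The NC1 arrays 4 to 6 differed from NC1 1 to 3 in 1850 genes. Remaining differences between arrays in the distribution of their values are argued against as the whole cause, since 1570 of these genes were still called after a second quantile normalization. An effect of the submitters' own normalization is not tested by this. A single outlying array is argued against as well, since at least 1044 were still called with any NC1 array left out. A batch that the treated arrays share stays open. It would give a positive r between the differences of mimic and siRNA arrays and those of the NC1 parts, and Pearson r across genes was 0.372. Other causes of a positive r were not tested. Of 100 pairs of splits the others gave at most 0.290. Those splits mix arrays of both groups and hold less of either difference, so their lower r does not speak for a batch. The 10 splits of the 6 NC1 arrays are too few for a share under 0.05 (973 genes in the real split with these arrays alone, 0 at most in the others). No biological explanation was tested, since the labels name no difference between these arrays.

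The interferon list was higher with the miR-138 mimic than with all NC1 arrays. NC1 and SIN3A siRNA were transfected RNAs too, so transfected RNA alone, whatever its sequence, would give no rise over them. Whether there was such a rise cannot be told here. The median over SIN3A siRNA was 0.54 (camera adjusted p = 0.524 with an estimated correlation). With the set as a block it was 1.14 (camera adjusted p = 8.14e-05 with an estimated correlation), but the sets were inferred from the values. Between NC1 4 to 6 and NC1 1 to 3, given the same RNA, the median differed by -0.71. A low level in NC1 4 to 6 alone cannot be told apart from a rise with the mimic: the median over NC1 1 to 3 was 0.16 (adjusted p = 0.112), and the labels do not say which NC1 arrays were run with the mimic. Only the order in which the samples are listed puts NC1 4 to 6 beside the mimic. An effect of the miR-138 sequence itself stays open as untested.

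CFTR was lower with SIN3A siRNA. A general loss of epithelial junction and polarity transcripts is argued against by that list, whose median was 0.051. Epithelial transcripts of other kinds are not covered by it. Secretory airway markers had a median of -0.21 with the set as a block (camera adjusted p = 1.61e-05), but 0.07 against NC1 4 to 6 (camera adjusted p = 0.122). Remaining differences between arrays in the distribution of their values are argued against by the CFTR change after a second quantile normalization, -1.37. The submitters' own normalization is not tested by this. Whether CFTR mRNA follows SIN3A mRNA cannot be told: CFTR was 0.60 higher with the mimic than with the siRNA with the set as a block (adjusted p = 0.120), where SIN3A fell further with the mimic (-1.13) than with the siRNA (-0.59), and 0.95 higher without the block (adjusted p = 0.00932). Effects of the siRNA on other transcripts, and effects of SIN3A protein, were not tested.

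Other splits of the 9 arrays of a comparison were counted with those arrays alone. For genes with SIN3A siRNA 2 of 84 splits, the real one included, gave as many calls (357 genes in the real one). The highest other, 1158, was the split that sets NC1 4 to 6 apart, which points to a structure of the arrays, and the blocked count was 1050. With such a structure the arrays are not exchangeable, so the low share of splits does not exclude chance. For genes with the mimic 3 of 84 splits, the real one included, gave as many calls (92 genes in the real one). The split that sets NC1 1 to 3 apart gave 1241 and the one that sets NC1 4 to 6 apart 367, the same structure, and the blocked count was 642. Chance is not excluded there for the same reason. For lists chance could not be excluded either, with 8 called in the real split and 23 in the highest other for the siRNA (45 of 84 splits as large), and 14 and 22 for the mimic (14 of 84). Between the interventions the 10 splits are too few for a share under 0.05 (1474 genes in the real split, 0 in the highest other, 1 of 10 as large). For the NC1 parts the real split was likewise the 1 of 10 as large.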

How the results depend on the processing

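Among the tests here, those with the array set as a block, with NC1 3 and 6 both left out, with the lists, the correlation or the NC1 parts under 1 array less, and of SIN3A and CFTR under other normalizations, filters, probe set choices or groups alone were chosen after the results were seen, while the comparison of the NC1 parts itself was planned before. The cause of a change was not tested except where the setting itself shows it (fewer arrays, more probe sets, a stricter threshold). The array values carry the submitters' background correction, so how far a dim probe set stood above its background is not known here, and a gene that was not called is not shown to be unchanged. The seed-site alternatives were not run. Over all settings, 168 results for named genes and lists stayed on their side of the threshold 2997 times, lost their call 628 times, gained one 80 times and turned direction 38 times. Each of the 38 was a list. Lists were followed over all settings where they were called with all NC1 arrays or with the set as a block, 35 results in the contrasts with NC1. Of the other 12 (siRNA) and 13 (mimic), 1 and 0 turned against NC1 1 to 3, 5 and 6 against NC1 4 to 6 and 1 and 6 with the block, with 0 of them called there (camera, lowest adjusted p 0.198). Between the interventions 14 of 30 lists turned with the block, 2 of them called both ways (glycolysis and cholesterol). Of 121 named calls 43 stood whichever array was left out and 78 were lost without at least 1 array. Of 12 named values that were not called 7 were called in some such fit.

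Several counts stayed within 1.5 times of 739 (SIN3A siRNA), 192 (mimic), 289 (mimic against siRNA) and 54 (shared). They were 800, 249, 363 and 70 after a second quantile normalization, 692, 159, 258 and 40 with arrays centred, 780, 239, 370 and 69 without the lowest 33.3% of genes, and 738, 188, 293 and 52 with probe sets averaged. Centring moved the siRNA split from 433 higher and 306 lower to 486 and 206. Lower calls outnumbered higher ones without NC1 3 (488 higher and 545 lower), without NC1 3 and 6 (374 and 477) and against NC1 4 to 6 alone (1162 and 1406). They also did with array weights (724 and 725) and a fold of at least 1.5 (101 and 109). The other settings kept more genes higher than lower. A trended robust variance gave 700, 183 and 286. SIN3A fell with the siRNA at an adjusted p of 9.23e-06 to 0.0725 over the alternatives. CFTR fell with it at 9.80e-07 to 0.00361, called in each. CFTR with the mimic was lower in each alternative (adjusted p 0.00493 to 0.568), and SIN3A with the mimic too (3.19e-05 to 0.202).

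Testing all probe sets gave 359 (siRNA), 88 (mimic), 115 (between them) and 17 shared, with SIN3A at -0.83 with the mimic (adjusted p = 0.108). More tests share the correction there. Only the groups compared gave 357 and 92, with SIN3A at -0.83 (adjusted p = 0.0880), from fewer arrays. Without moderation the counts were 327, 75 and 125, with array weights 1449, 576 and 1396, with a fold of at least 1.5 as well 210, 90 and 151, and at an adjusted p under 0.01 they were 179, 59 and 58. The second quantile normalization brought CFTR with the mimic to -0.47 (adjusted p = 0.0339). Of 133 named results 45 lost their call with all probe sets, 8 with the quantile normalization and 10 with centring. Of 123 in the groups compared 40 did.

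With the replicate number as a block (NC1 1 to 3 alone share numbers with the treated arrays) the counts were 708, 1281, 830 and 310 shared. The numbers were not taken to pair the arrays: residuals of arrays with the same number had a mean correlation of -0.05 (NC1 1 to 3 and mimic), 0.02 (siRNA and mimic) and 0.00 (NC1 1 to 3 and siRNA). A pairing of the other NC1 arrays with the mimic arrays was not checked.

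Against NC1 1 to 3 alone, 1415 genes were called with the mimic, 951 between the interventions and 382 shared, and 17 lists with the siRNA. Lists that turned were, with the siRNA, NF-kB (adjusted p = 0.000112), glycolysis (0.000786) and cholesterol (0.0311), and with the mimic histones (0.0715), reported targets (0.853) and NF-kB (0.000531). Against NC1 4 to 6 alone the counts were 2568, 877, 1505 and 574 shared, and CFTR with the mimic was at -0.57 (adjusted p = 0.00493). Here SIN3-HDAC (0.518), CFTR folding (0.198), secretory airway (0.122) and interferon (0.000154) turned with the siRNA, and secretory airway (0.853) and cholesterol (1.85e-05) with the mimic. Of the named results 17 lost and 5 gained a call against NC1 1 to 3, and 1 and 9 against NC1 4 to 6. Without both NC1 3 and 6 there were 635 genes between the interventions, CFTR with the mimic was at -0.53 (adjusted p = 0.0220), and SIN3-HDAC (0.894) and CFTR folding (0.874) turned with the siRNA.

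The set as a block left 642 genes with the mimic, 107 shared, a correlation of 0.15 between the interventions, 16 lists with the siRNA and CFTR with the mimic at -0.57 (adjusted p = 0.0188). NF-kB (0.000106), glycolysis (0.000737) and cholesterol (0.0339) turned with the siRNA, and secretory airway (0.850) and cholesterol (4.14e-05) with the mimic. An estimated correlation in that fit left 2 and 6 lists, with adjusted p 0.0216, 0.138, 0.336, 0.957 and 0.0714 for these 5. Of the named results 20 lost and 8 gained a call with the block. With each intervention against its own part of the control the correlation was 0.15, the same estimate as with the block. With the opposite assignment it was -0.23. Without the block an estimated correlation left 0 lists for the siRNA and 0 for the mimic (4 each at an unadjusted p under 0.05), and fry 4 and 3.

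Over the alternatives the adjusted p with the siRNA ran from 3.96e-06 to 0.983 for NF-kB, 0.000737 to 0.983 for glycolysis, 1.60e-09 to 0.742 for cholesterol, 0.0274 to 0.992 for SIN3-HDAC and 0.0239 to 0.983 for CFTR folding. It ran from 1.61e-05 to 0.824 for secretory airway and 9.08e-23 to 0.824 for interferon. With the mimic it ran from 9.53e-28 to 0.514 for histones, 0.000168 to 0.853 for reported targets and 6.33e-11 to 0.982 for NF-kB. Secretory airway ran from 4.41e-06 to 0.957 and cholesterol from 2.77e-06 to 0.967.

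Leaving out 1 array gave 165 (siRNA 3) to 1033 (NC1 3) genes with the siRNA, and 254 and 191 without siRNA 1 and 2. The mimic had 39 (mimic 1) to 264 (NC1 3), with 55 and 65 without mimic 2 and 3 and 124 and 122 without siRNA 1 and 2. Between the interventions there were 58 (mimic 2) to 568 (NC1 3), with 77 and 93 without mimic 1 and 3 and 96, 76 and 59 without siRNA 1, 2 and 3. Shared were 10 (mimic 1) to 86 (NC1 3), with 15 and 19 without mimic 2 and 3, 16, 16 and 18 without siRNA 1, 2 and 3, and 28 without NC1 6. Between the NC1 parts there were 1062 (NC1 5) to 2382 (NC1 1), and 1149 without NC1 4. SIN3A was at -0.996 (NC1 3) to -0.80 (NC1 4) with the siRNA and -0.94 (NC1 3) to -0.75 (NC1 4) with the mimic, and CFTR with the mimic at -0.49 (NC1 3, adjusted p = 0.0245) to -0.33 (NC1 4). The correlation was 0.33 (siRNA 2) to 0.41 (NC1 1). With 1 array less, the lists that turned had an adjusted p of 0.307 to 0.992 (SIN3-HDAC), 0.464 to 0.983 (CFTR folding), 0.356 to 0.983 (NF-kB) and 0.519 to 0.983 (glycolysis) with the siRNA. With the mimic these were 0.182 to 0.982 (NF-kB) and 0.145 to 0.967 (cholesterol). Lists called were 7 to 10 with the siRNA and 11 to 14 with the mimic. Of the named results 49, 56 and 59 lost their call without siRNA 1, 2 and 3, 36, 39 and 32 without mimic 1, 2 and 3, and 2 to 19 without an NC1 array.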

Other observations

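The lists in this part were fixed before the data were examined, and the tests with the array set as a block were chosen after the results were seen.

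With SIN3A siRNA, 2 of 36 genes of the G2/M phase fell and 0 rose: MAD2L1, a spindle checkpoint gene (log2 -0.85, SE 0.16, n = 3 against 6 arrays), and FOXM1 (-0.39). The list was not called (adjusted p = 0.136), and its median was 0.04 against NC1 1 to 3 and -0.24 against NC1 4 to 6. Of 27 MYC targets and ribosome biogenesis genes 2 rose and 0 fell: POLR1C, a subunit of RNA polymerases I and III (0.52, with 0.32 against NC1 1 to 3 and 0.72 against NC1 4 to 6), and DDX21 (0.39). Adjusted over the list alone 5 were higher (list adjusted p = 0.0824, and 0.00278 with the set as a block). MAD2L1 lost its call without SIN3A siRNA 3 (adjusted p = 0.0551), and POLR1C without any siRNA array (highest 0.110). FOXM1 lost it without any siRNA array, NC1 4, 5 or 6, or mimic 2 (highest 0.175) and with the set as a block (0.107). DDX21 lost it without any treated array, NC1 2 or NC1 6 (highest 0.173).

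Among 39 neuronal genes repressed by REST, a repressor that recruits SIN3A, the adhesion gene NCAM1 fell with SIN3A siRNA (-0.48) and 0 rose (list adjusted p = 0.232). Of 38 genes of epithelial junctions and polarity the transcription factor gene GRHL1 rose (0.46, SE 0.09) and 0 fell (list adjusted p = 0.389). NCAM1 lost its call without any siRNA array or NC1 2, 4, 5 or 6 (highest adjusted p = 0.123) and with the block (0.0912), and GRHL1 without SIN3A siRNA 2 or 3 (highest 0.0929). Of 25 reported miR-138 targets SIN3A fell and RHOC rose (0.34, list adjusted p = 0.751). RHOC kept its call without NC1 1 alone among the 12 arrays (highest adjusted p = 0.209) and lost it with the block (0.101). No member passed by limma among 20 genes of cholesterol biosynthesis (median -0.11, list adjusted p = 0.0610), 33 of glycolysis and hypoxia (-0.01, 0.940) and 22 of RNA interference (0.03, 0.262, with 2 higher adjusted over that list alone).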
